A study of Mus musculus with 6 samples.

How the data were processed

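The samples were 3 YBX1 immunoprecipitates and 3 inputs from untreated BaF3 cells with JAK2 V617F, 6 libraries in all. They were grouped by the titles in the labels, which also number the replicates. The files used were 3 tables of peaks, 1 for each immunoprecipitate, and 3 lists of peak summits.

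Reads were trimmed with Trim Galore and peaks were called with MACS2 on GRCm38, per the submitters' processing notes. The aligner was not given in the sources used here, and neither was the handling of reads that fit several places. Peaks were called per replicate against the input of the same number with MACS 2.1.1.20160309, per the file headers. The headers give no shifting model, a fragment extension of 160 bp, a q threshold of 0.01, a genome size of 2652783500 bases, 1 tag kept per position and strand, and the larger library scaled down to the smaller. Extended tags can therefore reach a pileup of at most 320, and the highest pileups were 320, 302 and 289.3. Before this filter the immunoprecipitates held 90.3 M, 92.4 M and 94.4 M tags, of which 25.8%, 26.0% and 26.1% were removed as repeats. The inputs held 152.5 M, 115.9 M and 115.7 M, of which 42.6%, 39.2% and 42.1% were removed. The input was scaled by 0.765 in replicate 1 and 0.970 in replicate 2, and the immunoprecipitate by 0.961 in replicate 3.

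The pileup is a signal, the number of extended tags over the summit, per the file headers in units of tags after scaling. The fold is the authors' ratio of pileup to local input level, with 1 added to each. The −log10 p and −log10 q values are the deposited output of the caller. Summit positions and −log10 q in the deposited summit lists were identical to those in the tables for all 7053, 2628 and 2827 peaks. Each value belongs to a peak that passed the threshold, so these lists hold no values for regions that were not called.

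The local input level behind each fold was recovered by solving the fold for it. Checked against the deposited values, the −log10 p recomputed from it under a Poisson distribution differed from the deposited one by a median of 9.42e-05, 8.38e-05 and 0.00163. It was divided by the genome-wide level, which is the kept tags times the extension over the genome size. Peaks below 5 times that level were called low-input, a limit set after the values were seen.

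Lists were merged where peaks overlapped by at least 1 bp, and a region counted as shared when at least 2 lists had a peak in it. For the overlap tests, the peaks on the chromosomes were placed at random 1000 times on their own chromosome with lengths kept. The design had planned to leave out assembly gaps. With no genome sequence used here, positions were drawn from the first to the last annotated gene or peak of a chromosome, gaps included, and the expected numbers per chromosome used the same spans. Gaps inside these spans raise the expected number on chromosomes that have many.

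Genes came from a RefSeq table of GRCm38.p6 with 1 span per gene, and 21775 protein-coding genes were used. The 340 entries that start below 3 Mb on chromosomes other than Y seem to carry scaffold or patch positions under a chromosome's name and were left out. The table gives no strand and no exons. The planned promoter window, 1 kb around transcript starts, was replaced by 1 kb around either end of a protein-coding gene, and classes by exon, intron and untranslated region were not analysed here. The CCAAT motif, base composition and repeat content of the regions, and tests matched on GC content, needed a genome sequence and were not run.

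Shares of regions by position were compared with 1000 random placements, two-sided. Gene lists, 20 in all, were fixed before the data were examined, and were tested by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment. Of 1939 names, 1937 were matched. Gene spans were tested against 10000 random lists matched on decile of gene length. Numbers per chromosome were tested by exact binomial tests. Shares of single lists have 95% Wilson intervals, which cover counting error only, and values over the 3 lists are given as mean ± SD.

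The named regions were set by a rule fixed before the data were examined. Regions in all 3 lists were ranked by the worst of their ranks by fold within the lists, each divided by the length of the list. The rule took the 20 best at gene ends, of which there were 5, and the 10 best elsewhere. It also took 12 fixed genes whatever their values and up to 4 members of each gene list. Values of some single genes and regions are not reported here. The tests were run first on simulated data. All 500 regions planted in the 3 lists were recovered, which was certain because they were shifted by less than a peak width. A gene list planted with regions at 10 of 40 members passed, and 1 of 20 unchanged sets passed the permutation test of gene ends at p = 0.05. The planted sets do not measure the power of the tests in these data.

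Alternatives were an overlap of 50% of the shorter peak, regions in all 3 lists or in any list, a −log10 q of at least 5, a fold of at least 5, lists of equal length, intervals of 200 bp around summits, autosomes and X only, windows of 500 bp and 3 kb, all annotated genes, and each replicate left out. Peaks on scaffolds outside the chromosomes entered the merging but not the comparisons with genes or chromosomes. The work used python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.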

Results

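YBX1 is a Y-box protein with a cold shock domain that binds DNA and RNA. Its binding to chromatin was measured by chromatin immunoprecipitation followed by sequencing in untreated BaF3 cells, a mouse cell line derived from pro-B cells, that carry the activated kinase mutant JAK2 V617F. The data were 3 YBX1 immunoprecipitates and 3 input libraries, numbered 1 to 3, and the authors had called peaks for each immunoprecipitate against the input of the same number. The peaks therefore came as 3 lists, called list 1, list 2 and list 3 here, each given by position on GRCm38. After the caller's removal of duplicates, the immunoprecipitates held 67.0 M, 68.3 M and 69.7 M tags and the inputs 87.6 M, 70.4 M and 67.0 M. The labels do not say whether the replicates came from separate cultures, so spreads between the lists may be technical. The labels name no control antibody and no cells without YBX1, and the only background was the input.

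The first question was where the 3 lists placed YBX1 on the genome, and how strongly. The highest fold enrichment over input in list 1, 10.9, lay 20.7 kb from Insig1, which encodes a regulator of sterol synthesis, and the same region had a fold of 5.66 in list 2. Other regions with high folds in both lists 1 and 2 lay 28.3 kb from Dpp10, at 10.1 and 5.40, and 115.3 kb from Foxl1, a forkhead transcription factor gene, at 6.88 and 6.84. A region 691.1 kb from Fat4 had folds of 5.94 and 8.59. These regions were chosen after their values were seen, and none of the 4 had a peak in list 3. Their pileups ran from 27 to 64, against medians of 212 in list 1 and 191 in list 2. The local input behind the folds near Insig1, Dpp10, Foxl1 and Fat4 was 1.00, 1.06, 1.26 and 1.73 times the genome-wide level. Near Insig1 this was the lowest level in either list. The 4 regions were unlike most peaks. The median fold was 1.78 in list 1, 1.75 in list 2 and 1.80 in list 3, or 1.77 ± 0.0229 (SD, n = 3), and 68.3% ± 2.49 (SD, n = 3) of the peaks of a list had a fold under 2. A fold of at least 5 was reached by 16, 23 and 22 peaks.

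List 1 held 7053 peaks, list 2 held 2628 and list 3 held 2827, and the inputs behind them had been scaled by 0.765, 0.970 and 1. The median peak width was 255, 264.5 and 266 bp. The folds and −log10 q values are the authors' own for each peak. They were ranked only within a list, while thresholds of 5 were applied to all lists alike. At the median peak, the local input level that the caller had set against the pileup was 28.2, 26.4 and 25.2 times the genome-wide level, or 26.6 ± 1.49 (SD, n = 3). Peaks with a local input below 5 times the genome-wide level, called low-input peaks below, numbered 176, 200 and 143, which was 2.50%, 7.61% and 5.06% of the lists. Their median folds were 3.19, 3.08 and 3.15, against 1.76, 1.71 and 1.77 for the remaining peaks. The folds of the 2 sets are not free to be alike, since the caller's limit on tags per position allows a fold of at most 2.79, 2.93 and 3.00 at the median local input of lists 1, 2 and 3.

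**Figure D1:**
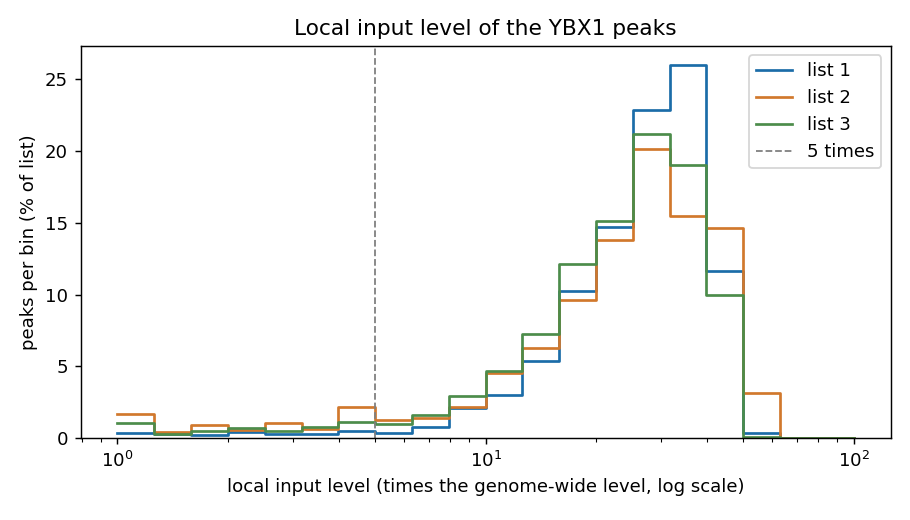
Percent of the peaks of each list (vertical axis) by local input level in multiples of the genome-wide level (horizontal axis, log scale), with 1 line per list and a dashed line at 5 times. The medians lie at 28.2, 26.4 and 25.2 times, and 2.50%, 7.61% and 5.06% of peaks lie below 5 times.

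The next question was which regions were found in more than 1 replicate. Of the regions found in all 3 lists, 2 of the 3 best ranked by fold lay in the same gene, Fam91a1, whose product acts in vesicle traffic to the Golgi. One spanned bases 58438456 to 58439543 of chromosome 15, with folds of 3.67, 5.20 and 7.28 in lists 1, 2 and 3, and the other spanned 58439853 to 58440457, with folds of 3.5, 4.51 and 7.53. A region in Cab39l, at 59445760 to 59446013 on chromosome 14, had folds of 4.71, 4.12 and 4.70. A region at 49391706 to 49391910 on chromosome 18, with 304.3 kb to the nearest protein-coding gene, Dtwd2, had folds of 7.21, 7.08 and 3.85. In Abcc1, which encodes a drug efflux transporter, the region at 14441718 to 14441989 on chromosome 16 had folds of 3.37, 3.52 and 2.77, and at a −log10 q of at least 5 it remained in 1 list.

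The other regions among the 10 best ranked lay outside protein-coding genes. On chromosome 5, a region at 49754604 to 49754881 was 205.2 kb from Adgra3, an adhesion receptor gene, with folds of 3.67, 3.13 and 3.48. Another, at 4601368 to 4601766 on the same chromosome, was 152.3 kb from the Wnt receptor gene Fzd1, with folds of 3.24, 2.87 and 2.78. The region at 56947650 to 56948093 on chromosome 15 was 253.3 kb from Has2, a hyaluronan synthase gene, and had folds of 3.45, 3.09 and 3.98. The regions nearest to Arrdc3, at 80024392 to 80024999 on chromosome 13, and H2al1n, at 14570473 to 14570798 on chromosome X, were 858.7 kb and 359.0 kb away, with folds between 2.65 and 3.07. The gene table used here gives spans without exons, so a position inside a gene could not be split into exon and intron.

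Merging the lists gave 8156 regions, of which 3048, or 37.4%, held peaks of at least 2 lists and 1291, or 15.8%, held peaks of all 3. Random placement of the lists on their own chromosomes gave a mean of 9.58 regions in at least 2 lists and never more than 21. The one-sided permutation p of 0.000999 was the smallest that 1000 placements can give. The placements did not keep the local input level of the peaks. Lists confined to the same overrepresented sequence would overlap more than random whatever the antibody, so the test does not show reproducible binding of YBX1. List 1 alone accounted for 4078 regions, list 2 alone for 510 and list 3 alone for 520. Lists 2 and 3 without list 1 shared 75 regions, lists 1 and 3 shared 933 and lists 1 and 2 shared 749. Leaving out list 1 took the number of regions found in both remaining lists to 1364.

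Of the peaks of list 2, 78.0% overlapped a peak of list 1 (95% Wilson interval 76.3 to 79.5), and of list 3, 79.1% did (77.5 to 80.5). In the other direction, 29.0% of list 1 was found in list 2 (28.0 to 30.1) and 31.6% in list 3 (30.5 to 32.7). List 3 held 52.1% of list 2 (50.2 to 54.0), and list 2 held 48.4% of list 3 (46.6 to 50.2). Random placement gave between 0.0545% and 0.150%, and each of the 6 one-sided permutation p values was 0.000999. These placements also left local input level out of account, so the same limit holds. The summits fell on the same base for 361 pairs of peaks in lists 1 and 2, 600 in lists 1 and 3 and 191 in lists 2 and 3.

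The peaks with the highest folds were not the ones most often found again. In the decile of each list with the highest folds, 35.4%, 36.1% and 54.4% of the peaks of lists 1, 2 and 3 overlapped a peak of another list. Across the 9 remaining deciles the share ran from 30.4% to 56.3% in list 1, from 81.0% to 97.3% in list 2 and from 74.2% to 92.2% in list 3. The decile with the highest folds also had the lowest median local input of each list, 13.2, 3.77 and 6.19 times the genome-wide level. Deciles by fold therefore also sort peaks by local input, and the effects of fold and input were not separated. Low-input peaks were found in another list in 19.9%, 15.0% and 23.8% of cases, against 42.8%, 86.0% and 84.7% of the other peaks. Fisher's exact test, two-sided and adjusted over the 3 lists by Benjamini-Hochberg, gave adjusted p = 3.19e-10, 4.53e-99 and 1.54e-54. These intervals and tests treat peaks as independent, yet 22.2%, 23.3% and 18.5% of the peaks of lists 1, 2 and 3 had the same length, summit offset, pileup and fold as another peak of their list.

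**Figure D2:**
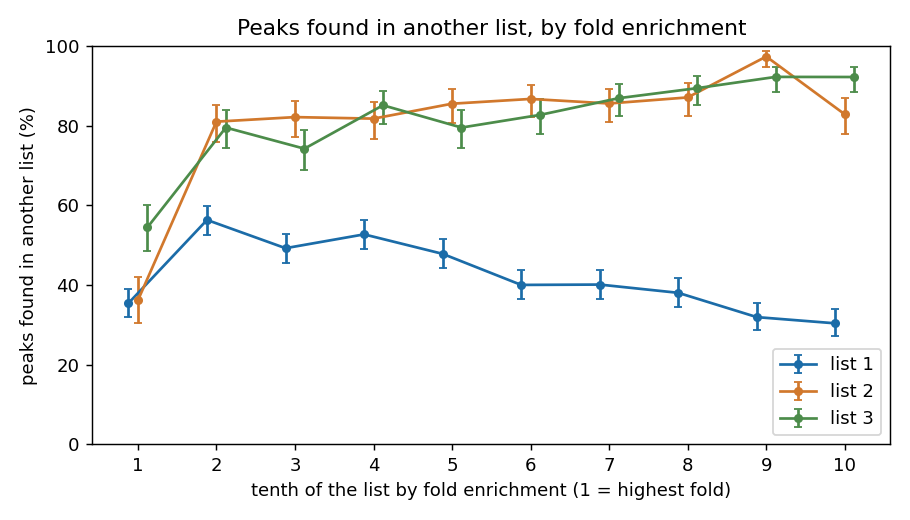
Percent of peaks that overlap a peak of another list (vertical axis) by decile of the list's own fold enrichment, from the highest at 1 to the lowest at 10 (horizontal axis), with 1 line per list and bars for the 95% Wilson intervals. The first decile stands at 35.4%, 36.1% and 54.4%, below every other decile in lists 2 and 3.

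Where YBX1 regions lay relative to genes was compared with random positions on the same chromosomes. Few regions were at gene ends. Among regions in all 3 lists, 5 had their midpoint within 1 kb of an end of a protein-coding gene. These were at Spin2d and Gm52416 on chromosome X, 4930467E23Rik on chromosome 8, Gm11127 on chromosome 17 and Pvr, an adhesion receptor gene, on chromosome 7. The Spin2d region, at 73174538 to 73174957, lay outside the gene, 555 bp from its nearer end, and had folds of 2.23, 1.90 and 2.02. The Gm52416 region, at 72876718 to 72877015, had folds of 1.98, 2.01 and 1.73, and the one at 19752561 to 19752958 in 4930467E23Rik had 1.68, 1.98 and 1.73. The region 752 bp from Gm11127, at 36054935 to 36055194, lay inside Gm6034, whose span also holds Gm11127, and had folds of 1.84, 1.46 and 1.45. The region at 19902487 to 19902749, 960 bp from Pvr, had folds of 1.79, 1.44 and 1.43. At a −log10 q of at least 5, the regions at Pvr and 4930467E23Rik remained in 1 list and the one at Gm11127 in 2.

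Over all shared regions on the chromosomes, 26 of 3040, or 0.855% (95% Wilson interval 0.584 to 1.25), were at an end of a protein-coding gene. Random placement gave 2.99% ± 0.312 (SD of 1000 placements). The share was 0.388% for regions in all 3 lists and 0.514% without replicate 1. Inside protein-coding genes lay 23.0% of the regions against 39.2% ± 0.915 at random, and inside long noncoding RNA genes 5.23% against 8.35% ± 0.498. Each difference had a two-sided permutation p of 0.002, the smallest that 1000 placements can give, and an adjusted p of 0.0025 over the 5 classes. Inside annotated pseudogenes the share was higher than at random, 1.64% against 1.04% ± 0.179 (adjusted permutation p = 0.0040). For regions in all 3 lists it was 1.63%, with an unadjusted permutation p of 0.0559. The single lists gave 0.938% ± 0.177 at gene ends, 24.4% ± 0.780 inside protein-coding genes and 2.08% ± 0.362 inside pseudogenes (SD, n = 3). The median distance from a shared region to the nearest end of a protein-coding gene was 65.3 kb, against 49.9 ± 2.31 kb at random (two-sided permutation p = 0.002), and 41.2% of regions were over 100 kb away. Random positions were not matched on local input, which at the median shared region was 27.4 times the genome-wide level. These comparisons therefore do not tell the position of YBX1 from that of sequence overrepresented in input.

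**Figure D3:**
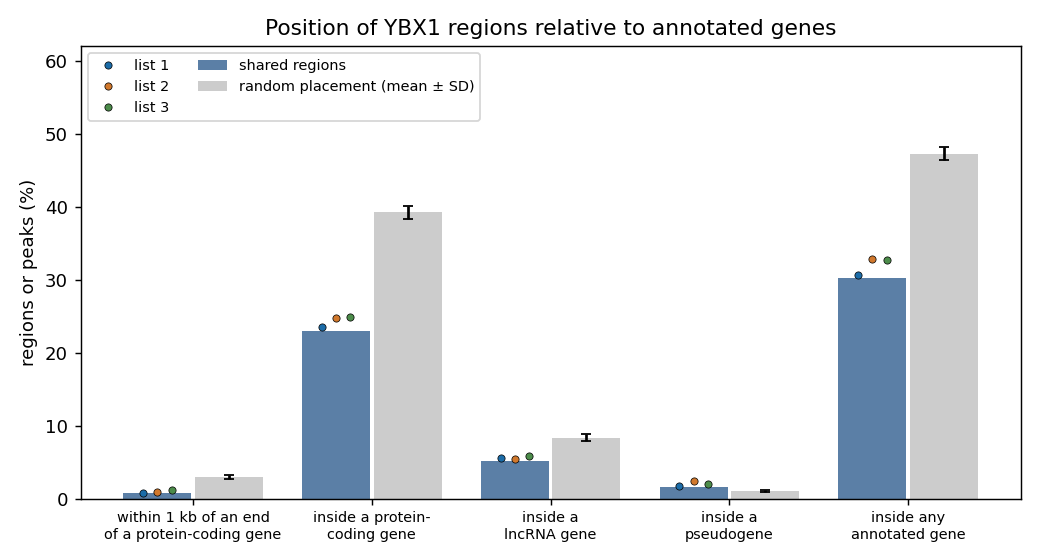
Percent of shared regions (blue bars) and of the peaks of each list (points) in each class of position (horizontal axis), beside random placements of the shared regions (grey bars, mean ± SD of 1000). Shared regions stand at 0.855% against 2.99% at gene ends and 23.0% against 39.2% inside protein-coding genes, and are above random only inside pseudogenes, 1.64% against 1.04%. Random placements were not matched on local input level.

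Gene ends were more common among low-input peaks. They made up 8.52%, 4.0% and 5.59% of the low-input peaks of lists 1, 2 and 3, or 6.04% ± 2.29 (SD, n = 3), against 0.596%, 0.618% and 0.894% of the other peaks. Fisher's exact test gave adjusted p = 9.97e-12, 1.77e-04 and 1.77e-04. Of these 31 peaks 4 were found in another list, those at Gm32584 and Gm7762, and 8 of the 15 in list 1 had identical copies. Without peaks that have an identical copy, an alternative added after seeing the data, the shares were 4.64%, 4.42% and 5.93% (adjusted p = 1.35e-04, 1.35e-04 and 2.82e-04 by the same exact test). The genes, named here after their values were seen, included 5 Btbd35f genes on chromosome X, the vomeronasal receptor genes Vmn1r248, Vmn1r259 and Vmn2r47 on chromosome 7, and the major urinary protein gene Mup15. In list 1, the peaks at Gm14594, Gm14596, Gm16405 and Gm16430 on chromosome X all had a fold of 2.64 and a pileup of 46. In list 2, those at Vmn1r248 and Vmn1r259 both had a fold of 3.79 and a pileup of 21, but did not count as identical copies.

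The next question was which gene groups had YBX1 regions. No gene list fixed in advance passed a test against other genes. A shared region overlapped the 1 kb windows around the ends of 27 of 21775 protein-coding genes, or 0.124%. Among the 765 distinct genes of the 19 lists other than olfactory receptors, 0 had one. These lists covered JAK-STAT and MAPK-ERK-MNK components, STAT5 response genes, splicing factors, cytosolic ribosomal proteins, translation factors, Y-box and cold shock proteins and reported Y-box or CCAAT targets. They also covered cell cycle genes, apoptosis regulators, histones, oxidative phosphorylation, heat shock and unfolded protein response genes, and markers of B lineage, myeloid, mast or erythroid or megakaryocyte, T and NK, hepatocyte and neuronal cells. Of 1109 olfactory receptor genes 2 had a region, Olfr108 and Olfr38, against 1.38 expected. Fisher's exact test called 0 of 20 lists at adjusted p under 0.05, and 0 had an unadjusted p under 0.05. At most 0.102 members per list were expected, or 1.38 for olfactory receptors. A lower share than in other genes was therefore not detectable in any list at this depth.

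Within the whole span of a gene and 1 kb on either side, 549 genes, or 2.52%, had a shared region. They included 5 of the 765 list genes: Abcc1 among the reported Y-box targets, Casp8, an initiator caspase, among apoptosis regulators, Apoh among hepatocyte markers, Adgre1 among myeloid markers and Map2 among neuronal markers. The span of 4 olfactory receptor genes held one, Olfr165, Olfr108, Olfr38 and Olfr631, against 1.47 in random lists matched on gene length (unadjusted permutation p = 0.0692). Against such lists 0 of 20 passed and 0 had an unadjusted p under 0.05. In a count of peaks in any single list, chosen after seeing the data, Ghr, Pias2 and Cbl among the 39 JAK-STAT components and Sos1, Gab2 and Map2k1 among the 50 MAPK-ERK-MNK components had a peak in their span, against 2.31 and 3.84 in matched random lists.

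Shared regions inside genes were spread over fewer and longer genes than the same number of random positions inside genes. The 700 regions with their midpoint in a protein-coding gene fell in 534 genes, against 648 ± 10.7 (SD of 1000 draws) with as many positions per chromosome drawn inside such genes. The median span of these genes was 184.0 kb, against 124.0 ± 7.96 kb. Both two-sided permutation p values were 0.002, the smallest that 1000 draws can give, and both tests were chosen after the data were seen. The draws were independent and not matched on local input, while shared regions can lie close together, as in Fam91a1. Such clusters alone lower the number of genes, so that number does not show a preference among genes. The genes with the most shared regions, 5 each, included Pkd2l1, Trak1, Etl4 and Csmd1. Per Mb of span these 4 genes held 49.7, 28.2, 5.55 and 3.04 regions. The span of Scd3, with 4 shared regions, lies inside that of Pkd2l1, so these regions count for both genes. Trak1 encodes an adaptor for mitochondrial transport, and Csmd1, with a span of 1643 kb, is among the long genes expressed in brain.

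None of the 12 genes fixed for a closer look, which included Ybx1 itself and members of the pathway in the series title, had a peak of any list within its span or 1 kb of it. The nearest shared region was 353.5 kb from Ybx1, 160.7 kb from its paralogue Ybx3, 1096 kb from Jak2 and 463.5 kb from Mknk1, the ERK-activated kinase of the title. It was 303.5 kb from Mknk2, 851.6 kb from Mapk3 and 129.4 kb from Eif4e, whose product is phosphorylated by the MNK kinases. For the STAT5 response genes it was 260.9 kb from Bcl2l1, 531.4 kb from Myc, 2205 kb from Pim1 and 184.3 kb from Mcl1. Across all protein-coding genes only 2.52% had a shared region in such a span, and shared regions numbered 1.14 per Mb of chromosome. With so few regions, the lack of a region at 12 genes does not set them apart from other genes.

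Chromosome Y had fewer shared regions than its length gives, and chromosome 7 had more. The test treats regions as independent, yet 27.2% of the shared regions held a peak with an identical copy in its list. Expected numbers came from span length alone, gaps included, and took no account of local input or chromosome copy number. The ratios therefore do not show a preference of YBX1 among chromosomes. On Y, 52 were found against 103.8 expected, a ratio of 0.501 (adjusted p = 3.94e-07, exact binomial test, two-sided, over 21 chromosomes), and the lists gave ratios of 0.438 ± 0.0724 (SD, n = 3). Without identical peaks the ratio on Y was 0.371. On chromosome 7, 199 were found against 162.5, a ratio of 1.22 (adjusted exact binomial p = 0.0438), and the lists gave 1.24 ± 0.0376 (SD, n = 3). Chromosome X had a ratio of 1.19 and did not pass (adjusted exact binomial p = 0.0696), although the lists gave 1.29 ± 0.0702 (SD, n = 3). With regions in all 3 lists, 0 chromosomes passed, with ratios of 0.637 on Y and 1.16 on chromosome 7. The call on chromosome 7 was also lost without replicate 1 (ratio 1.14, adjusted exact binomial p = 0.478) and without replicate 3 (1.14, adjusted p = 0.383). Without identical peaks, an alternative added after seeing the data, chromosome 7 did not pass (1.19, adjusted exact binomial p = 0.227) and X did (1.24, adjusted p = 0.0411). By the same exact test, X passed without replicate 1 (1.31, adjusted p = 0.0464) and without replicate 3 (1.25, adjusted p = 0.0327). Without replicate 3, chromosome 5 (1.30, adjusted exact binomial p = 0.0150) and chromosome 16 (1.32, adjusted p = 0.0375) passed too.

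**Figure D4:**
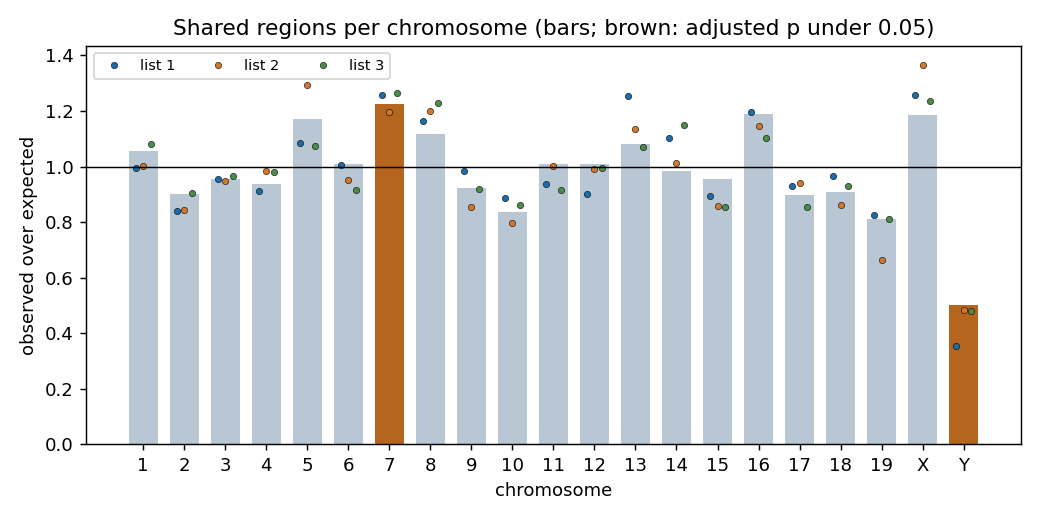
Observed over expected number of regions on each chromosome (horizontal axis), as bars for shared regions and points for the 3 lists, with a line at 1 and brown bars where the adjusted p is under 0.05. Chromosome 7 stands at 1.22, X at 1.19 and Y at 0.501.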

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

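Tests reported here were chosen after the results were seen, except the test of long stretches of copy gain, which was set before its value was known.

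Signal in sequence that the comparisons with genes and chromosomes left out was found on scaffolds outside the chromosomes, which held 37 peaks of list 1, 13 of list 2 and 13 of list 3. They merged into 52 regions on 16 scaffolds, of which 8 were in at least 2 lists and 3 in all 3. Their highest folds were 2.98, 3.02 and 2.67.

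The median YBX1 peak lay where the input was 25.2 to 28.2 times the genome-wide level, so most shared regions, including those at Spin2d, Gm52416 and Pvr, lay in sequence that is overrepresented in input. Gain of copy number over long stretches of chromosome was argued against. Low-input peaks lay within 100 kb of a high-input peak at least 1.04 times as often as random positions in every list, where such stretches would keep them apart. Reads from multi-copy sequence placed at every copy may account for part of the pattern: at least 18.5% of the peaks of each list shared length, summit offset, pileup and fold with another peak, against at most 1.41% in permuted lists. The largest such sets held 64 peaks on 20 chromosomes in list 1 and 70 on 20 in list 2. The origin of the remaining peaks stays open, and no biological explanation was tested, since no other antibody was compared.

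List 1 was 2.59 times as long as the mean of lists 2 and 3, and it alone held 4078 regions. More immunoprecipitate tags do not account for it, since replicate 1 had 67.0 M, the fewest of the 3. The input of replicate 1 was scaled by 0.765, and whether this lengthened the list stays open. With no input scaled down, 3580 of its peaks still passed the list's own lowest −log10 p, against 2198 in list 2 and 2826 in list 3, and the ratio fell to 1.43. Unscaled input can only remove peaks, most of them where the scale was lowest, so the fall does not decide it, and no biological difference between replicates was tested.

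Low-input peaks were found again in 19.9%, 15.0% and 23.8% of cases and lay at gene ends in 8.52%, 4.0% and 5.59%. Calls at random positions along the chromosomes were argued against as the whole cause. On the chromosomes, the lowest share found in another list was 15.2%, against at most 2.82% in any random placement. The placements were not matched on local input, and an overlap with any peak of another list counted. They therefore do not tell binding of YBX1 from sequence in which peaks recur whatever the antibody. For those at gene ends, reads placed at every copy of a gene family stay open. Of the 31 low-input peaks at gene ends 25.8% had an identical copy in their list, against 8.70% of the 483 others (Fisher's exact test, two-sided, p = 0.00627), but all 8 of these were in list 1, and without it 0 of 16 had one (p = 0.619). Without identical peaks the gene-end shares were 4.64%, 4.42% and 5.93%. This filter cannot decide the question, since peaks at copies of a family that differ in length or summit offset pass it. In list 2, the peaks at Vmn1r248 and Vmn1r259 had the same length, a fold of 3.79 and a pileup of 21, and still passed. No biological explanation was tested.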

How the results depend on the processing

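The alternatives without identical peaks and with low-input peaks alone, all those on regions inside protein-coding genes, and gene spans with a peak in any list were chosen after seeing the data. The 3048 shared regions stayed within 1.5 times under 50% overlap, 200 bp summit intervals, autosomes and X only, and without identical peaks. They also did so without replicate 2, at 2224, and without replicate 3, at 2040. They became 1291 in all 3 lists, 1961 at a −log10 q of at least 5 and 1833 with lists of equal length. At a fold of at least 5 there were 6, with low-input peaks alone 40, and without replicate 1 there were 1364. The 50% overlap moved each of the 6 pairwise shares by less than 2 percentage points.

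The share at gene ends stayed below random with the other windows, genes and thresholds run, and was 0.514% to 0.722% with a replicate left out, the lowest without replicate 1. With low-input peaks alone it reversed, at 5.0% against 2.85% at random, though not past the threshold (permutation p = 0.633). Inside protein-coding genes, low-input peaks alone gave 32.5% against 40.7% and no longer passed (permutation p = 0.360); the other alternatives passed. Only 40 regions were left in these tests.

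Gene lists that passed were 0 in every alternative run, by Fisher's exact test or matched random lists, and 0 had an unadjusted p under 0.05. The 27 genes with a region at an end became 64 with 3 kb windows, 5 in all 3 lists, 80 in any list, 15 at a −log10 q of at least 5, and 7 to 18 with a replicate left out (7 without replicate 1, 13 without replicate 3). The 2 chromosomes that passed became 0 in all 3 lists, and 2 to 4 with a replicate left out, 4 without replicate 3 (5, 16, X and Y). The ratio of chromosome 7 no longer passed in all 3 lists (1.16), without identical peaks (1.19) or without replicates 1 or 3, and ranged from 1.14 to 1.27 with a replicate left out. That of Y no longer passed in all 3 lists (0.637), where fewer regions were tested. Chromosome X, which had not passed, did so without identical peaks (1.24, adjusted exact binomial p = 0.0411). Otherwise the cause of these changes was not tested.

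No paired analysis was possible because inputs and immunoprecipitates with the same number enter only through the authors' peak calls, and no test compared the groups. Tests matched on GC content, the CCAAT motif and base composition were not run. With 3 lists, a region missing from a list shows only that it did not pass the caller's threshold at that depth.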

Other observations

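The regions named here were chosen after their values were seen. Shared regions with a low local input, taken as a median over their peaks below 5 times the genome-wide level, numbered 43, of which 9 were in all 3 lists and 13 lay inside a protein-coding gene. None of the 43 had an identical copy, but copies that differ in length or summit offset pass this filter. In list 3, the peaks near Ccm2l on chromosome 2 and Samd9l on chromosome 6 both had a fold of 3.13 and a pileup of 24.02.

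Several lay inside genes. In Bin2, expressed in blood cells, a region at 100647189 to 100647485 on chromosome 15 had folds of 4.56 in list 1 and 4.95 in list 3. In Arnt, which encodes the partner of the aryl hydrocarbon receptor, a region at 95472224 to 95472641 on chromosome 3 had folds of 3.37 in list 1 and 4.49 in list 2. In Fam135a, the region at 24088686 to 24089719 on chromosome 1 had folds of 3.67 in list 2 and 8.20 in list 3, the highest fold of list 3.

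A set of 6 regions had a fold of at least 5 in at least 2 lists. They were those near Insig1, Dpp10, Foxl1, Fat4 and Dtwd2 and the longer one in Fam91a1, and 1 of the 6 lay inside a protein-coding gene.

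Of the 2734 distances under 10 kb between neighbouring summits of list 1, the commonest was 828 bp, seen 34 times. In list 2 it was 1497 bp, seen 21 times among 416, and in list 3 it was 282 bp, seen 5 times among 477. Whether peaks were regularly spaced was not tested.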
